A study of Mus musculus with 24 samples.

How the data were processed

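Polyadenylated RNA was sequenced from cerebrum and cerebellum of C57BL/6J mice that carried a Polr3a mutation induced by tamoxifen at postnatal day 28 (P28), and from wild type mice that also received tamoxifen. Polr3a encodes the largest subunit of RNA polymerase III, which makes transfer RNAs, 5S ribosomal RNA and other short noncoding RNAs. RNA was extracted with Trizol, and a sequencing company prepared the libraries by polyA enrichment, so most RNA polymerase III products lack the tail that the libraries select. The 24 libraries form 6 groups of 4: cerebrum at P42, cerebellum at P42 and cerebrum at P75, each from mutants and wild types. The cerebrum groups at P42 held 2 males and 2 females each, the cerebellum groups held 2 males and 2 females (mutants) or 3 males and 1 female (wild types), and all P75 libraries came from males. Expression of sex-linked genes matched the labelled sex in 24 of 24 libraries. The labels do not say that every library came from a separate animal, nor whether a cerebrum and a cerebellum came from the same animal, so p-values here measure the spread between libraries.

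The deposited gene tables hold read counts for 54532 genes, as whole numbers with no scaling. The processing notes of the authors name HISAT2, DESeq2 and the mouse genome build mm10, without versions; the read counter and the annotation release are not given in the sources used here. Gene coordinates in the tables are those of mm10 (GRCm38). The authors also deposited a table per comparison with the output columns of DESeq2. Per the file headers these give the mean signal (baseMean, the mean of normalized counts), the log2 fold change, its standard error, which is another kind of value than a level, the Wald statistic as a score per gene, and a p-value with its adjusted p-value. The covariates and filters behind these tables are not stated. They were used only for comparison, and the sign of their log2 fold changes was checked against the counts.

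All tests started from the counts, in R 4.3.3. Each tissue and age was its own comparison of 4 mutant with 4 wild type libraries. Genes were kept by edgeR's filterByExpr with genotype as the group, libraries were scaled by TMM, and genotype was tested with edgeR 4.0.16 by the quasi-likelihood F test, two-sided, with sex as a covariate at P42. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences of the genotype effect between tissues at P42 and between ages in cerebrum were tested as interaction terms over 16 libraries each, with sex as a covariate. A difference between ages is also one of time since tamoxifen, 14 days at P42 and 47 days at P75. The count tables of P42 and P75 are separate, so an age effect by itself could not be told from a run effect and was not tested; the interaction sets each age against its own wild types. Log2 fold changes are given with their standard error (SE), and levels as counts scaled to a library total of 1000000 (CPM) with the standard deviation (SD) over 4 libraries; CPM of Polr3a, Esr1 and the short noncoding RNAs use the library total, those of other genes the TMM-scaled total. Where the wild type libraries held no count of a gene, the fold is a lower bound against a floor of 3 counts over the group; where they held 1 to 3 counts, it is a ratio of counts with a 95% interval. Such floors and intervals cover counting error only, and reads without molecular identifiers are not independent molecules.

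Gene lists of pathways, cell types and brain regions were fixed before the data were examined, as were the tests, most alternatives and the rule for naming genes. Of 46 lists, 45 had at least 5 measured members in some comparison and were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted within a comparison; a further list served the check of the sex labels. A list's call compares its members with all other genes. It was repeated with an estimated correlation and with fry, which asks whether the members move, on balance, one way. Beside each list stands the number of members past the gene test over all genes and, where it differs, the number past it when adjusted over the list alone. The rule named Polr3a, up to 4 members of each list with the smallest p, and up to 10 genes each way with the largest change among called genes with at least 1 CPM on average, no overlap of the groups and an approved symbol; for each interaction, 5 genes each way with the smallest p. Of the list symbols, 5 were not found in the tables.

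Alternatives were DESeq2 1.42.0, relative log expression scaling, no filter and a stricter filter (1 CPM in 4 libraries), the replicate number as a block, no sex term, an adjusted p under 0.01, and leaving out each library in turn. Those chosen after seeing the data were scaling by library size only, a marker level as a covariate, leaving out mutant replicates 3 and 4 of cerebrum at P42, males only, and fry. The genotype labels were also reassigned over all distinct splits of the 8 libraries of a comparison that the model could fit. In cerebrum at P42 the split of males against females could not be fitted beside the sex term, which left 34. Pairs of replicates in a group differed far beyond counting noise (chi-square per degree of freedom of 3.78 to 91.9), so none is a copy of another. Tested on simulated data with the spread of each comparison, the gene test recovered 35.2% of genes changed 2-fold in cerebrum at P42, 36.4% in cerebellum at P42 and 72.8% in cerebrum at P75, with 5.81%, 9.12% and 5.57% false calls. At 4-fold it recovered 81.2%, 80% and 92.4%. Simulated genes were drawn independently of each other, so these shares do not cover structure that many genes of a library share.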

Results

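The study profiled messenger RNA after adult induction of a Polr3a mutation, in cerebrum and cerebellum at P42 and again in cerebrum at P75. Each of the 6 groups held 4 libraries. Total counts per library (in units of 1000000) ranged from 13.8 to 23.2. Mutant and wild type groups spanned 15.5 to 21.6 and 18.1 to 23.2 in cerebrum at P42, and 14.1 to 23.1 and 13.8 to 16.8 in cerebellum. In cerebrum at P75 they spanned 16.9 to 19.5 and 15.7 to 20.5. All mice received tamoxifen. The labels do not say whether wild types carried the Cre transgene, so an effect of Cre itself is not separated from that of the mutation.

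The level of the mutated gene itself was compared first. Polr3a (ENSMUSG00000025280, chromosome 14, 24448696 to 24487058, mm10) had 37.6 ± 3.77 CPM in mutant and 39.5 ± 3.65 CPM in wild type cerebrum at P42 (SD, n = 4 each). In cerebellum it had 52.0 ± 6.23 and 51.2 ± 8.24 CPM, and in cerebrum at P75 32.7 ± 1.68 and 32.5 ± 3.04 CPM. Its log2 fold changes were -0.14 ± 0.11 (SE, adjusted p = 0.562), 0.10 ± 0.13 (adjusted p = 0.984) and -0.10 ± 0.09 (adjusted p = 0.542), so the transcript level did not tell mutants from wild types. A gene singled out after its values were seen did: Esr1, the estrogen receptor alpha gene (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614). It had 51.7 ± 10.9 against 4.50 ± 3.39 CPM in cerebrum at P42, 64.4 ± 16.8 against 1.83 ± 0.236 CPM in cerebellum, and 91.7 ± 34.3 against 5.74 ± 0.804 CPM in cerebrum at P75. All mutant libraries lay above all wild types in each comparison, with log2 fold changes of 3.56 ± 0.44 (adjusted p = 0.0716, which missed the threshold), 5.16 ± 0.23 (adjusted p = 6.0e-05) and 3.90 ± 0.23 (adjusted p = 1.1e-06).

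**Figure D1:**
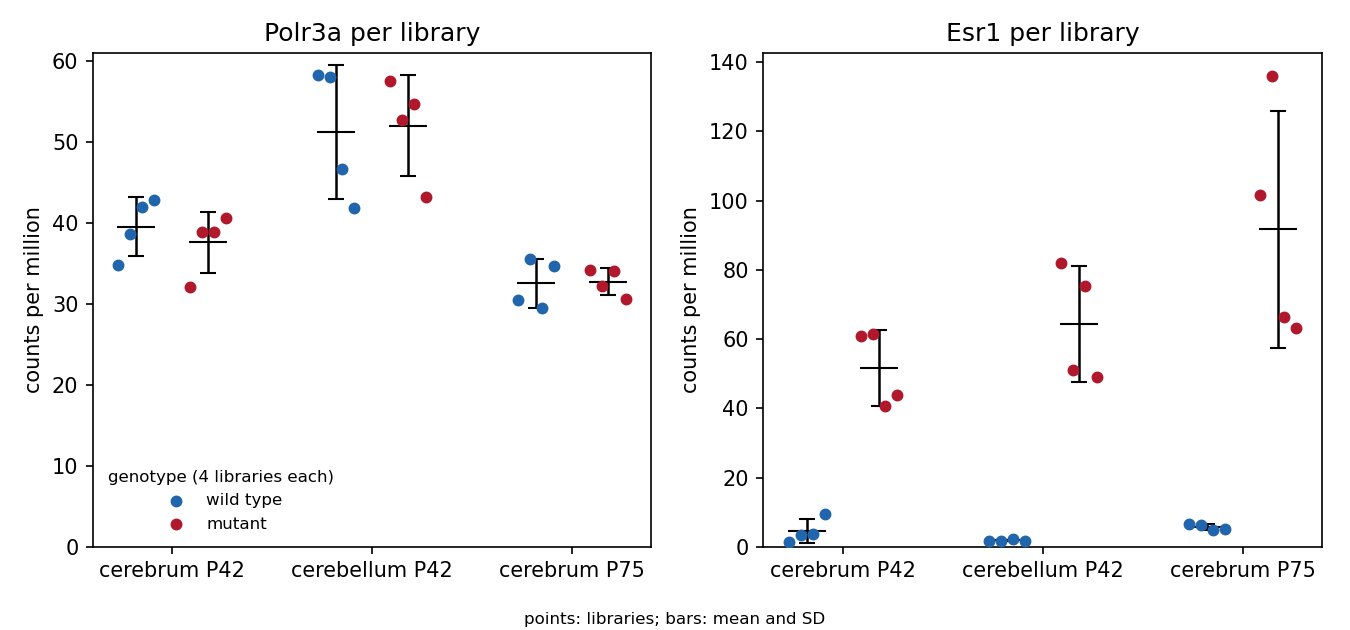
CPM of Polr3a and of Esr1 (vertical axes) in each library, by tissue, age and genotype (horizontal axis); points are libraries, bars the mean and SD of 4. Polr3a means lie between 32.5 and 52.0 in every group, whereas Esr1 means are 51.7 to 91.7 in mutants and 1.83 to 5.74 in wild types.

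The first question was which genes differed between mutants and wild types in cerebrum at P42. Slitrk6, which encodes a neuronal transmembrane protein (chromosome 14, 110748580 to 110755149), rose to 14.2 ± 3.19 CPM from 2.90 ± 0.897 CPM in wild types, a log2 fold change of 2.32 ± 0.24. Synpo2, an actin-binding protein gene (chromosome 3, 123076519 to 123236149), rose by 2.12 ± 0.24, and Wnt3, a secreted Wnt ligand gene (chromosome 11, 103774150 to 103817957), rose by 1.92 ± 0.22. Each had an adjusted p of 0.0476, with all 4 mutants above all 4 wild types. These 3 were the only genes of 18205 that passed, while 2299 had an unadjusted p under 0.05, DESeq2 called 233 (164 higher, 69 lower) and the table of the authors has 202 at an adjusted p under 0.05. Groups did not overlap for 6.41% of genes, where chance gives 2.86%.

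Among fixed lists in cerebrum at P42, 43 were tested and 18 called, 11 higher and 7 lower, and no list member passed the gene test over all genes. Markers of thalamus, hypothalamus and midbrain were higher for 26 of 26 members, with a median log2 fold change of 1.35 (adjusted p = 3.3e-13, but 0.542 with an estimated correlation); 12 passed when adjusted over the list alone. Prkcd, a thalamic kinase gene, had 2.69 ± 0.41 (adjusted p = 0.133) and Avp, the vasopressin gene, 3.65 ± 0.72 (adjusted p = 0.230). Their mean level per library was 2.70 and 2.52 in mutant replicates 3 and 4, 1.85 in replicate 2 and 0.10 in replicate 1, on a log2 scale where wild types spanned -1.1 to 1.0. Targets of ATF4, the transcription factor of the integrated stress response, were higher for 32 of 34 members, with a median of 0.50 (adjusted p = 1.3e-11, but 0.542 with an estimated correlation); 7 passed when adjusted over the list alone. Examples are Mthfd2 (1.27 ± 0.19, adjusted p = 0.133), Chac1 (1.77 ± 0.33, adjusted p = 0.230) and Slc7a3 (1.08 ± 0.18, adjusted p = 0.16), an enzyme of mitochondrial folate metabolism, a glutathione-degrading enzyme and an amino acid transporter.

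In the same comparison, cerebrum P42, cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, were higher for 19 of 23 members (median 0.13, or 0.20 with library size alone, adjusted p = 0.00257, but 0.542 with an estimated correlation; 0 passed over the list alone). Homeostatic microglia markers were lower for all but 3 of 21 members, with a median of -0.34, or -0.17 with the deep region covariate (adjusted p = 6.1e-05, but 0.448 with an estimated correlation); P2ry12, the microglial purinergic receptor gene, had -0.95 ± 0.13 (adjusted p = 0.112), and 3 members fell when adjusted over the list alone. Myelin and mature oligodendrocyte genes had a median of 0.44 (40 of 46 higher, adjusted p = 1.3e-10, but 0.63 with an estimated correlation; 11 over the list alone). Cortical and hippocampal excitatory neuron markers had a median of -0.68 (adjusted p = 1.8e-07, but 0.601 with an estimated correlation; 0 over the list alone) and synaptic genes -0.30 (adjusted p = 2.6e-06, but 0.63 with an estimated correlation; 0 over the list alone). These 3 medians were 0.16, -0.17 and -0.10 without mutant replicates 3 and 4, whose deep region markers were highest. The excitatory median also moved to -1.05 without mutant replicate 1 and -0.42 without replicate 3, and the myelin median to 0.29 without replicate 4. Interferon-stimulated genes were not called (median 0.12, adjusted p = 0.253), nor were RNA polymerase III subunits (median 0.15, adjusted p = 0.253), with 0 members past the gene test in both.

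Lists of basic cell functions were called as well in cerebrum P42, with 0 members past the gene test. Nuclear-encoded oxidative phosphorylation genes were higher for 72 of 77 (median 0.29, adjusted p = 4.1e-08, but 0.63 with an estimated correlation), and ribosomal proteins for 68 of 83 (median 0.21, adjusted p = 6.1e-05, but 0.711 with an estimated correlation). Mitochondrially encoded genes were lower, with 1 of 12 higher (median -0.28, adjusted p = 0.00429, but 0.63 with an estimated correlation), and p53 targets were higher for 17 of 23 (median 0.34, adjusted p = 0.00476, but 0.63 with an estimated correlation; 5 over the list alone). The nuclear median was 0.17 without mutant replicate 4, 0.14 without wild type replicate 4 and 0.19 with the deep region covariate. Ribosomal proteins had 0.32 without mutant replicate 1, and lost the call without wild type replicate 4 (0.094, adjusted p = 0.0627) and with the covariate (0.11, adjusted p = 0.118). The mitochondrial list had -0.43 without mutant replicate 1 and -0.18 without replicate 4. It lost the call without mutant replicate 2 (adjusted p = 0.0687), without wild type replicate 2 (adjusted p = 0.0604) and with the covariate (-0.084, adjusted p = 0.757). The p53 list had 0.56 without mutant replicate 3 and 0.65 with the covariate, and lost the call without replicate 1 (0.25, adjusted p = 0.234). Without mutant replicates 3 and 4 together the nuclear, ribosomal, mitochondrial and p53 medians were 0.12, 0.059, -0.13 and 0.57, and the ribosomal and mitochondrial calls were lost (adjusted p = 0.278 and 0.0673). Whether RNA quality lies behind these shifts was not tested.

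Limits of the P42 cerebrum calls were these. No gene remained without mutant replicate 2, 3 or 4, without wild type replicate 2 or 4 (0 each), without the sex term (0) or with library size alone as the scaling (0), 1 remained without wild type replicate 3, while 11 were called without mutant replicate 1 and 6 without wild type replicate 1. With the level of the deep region markers as a covariate, 0 genes and 12 lists were called, and the ATF4 median was 0.65. Slitrk6, Synpo2 and Wnt3 then had log2 fold changes of 2.08, 2.27 and 2.0, each with an adjusted p of 0.213. Whether a difference in dissection enters the rises of these genes stays open. Wnt3 was also lost with the replicate block (1.94, adjusted p = 0.0542). The myelin, excitatory neuron and synaptic lists lost their calls with this covariate (medians 0.15, -0.24 and -0.06, adjusted p = 0.0868, 0.107 and 0.243). The median of the deep region markers themselves was 0.66 without mutant replicates 3 and 4.

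The same question was asked in cerebellum at P42. Esr1 rose, as given above, and Col9a3, a type IX collagen gene (ENSMUSG00000027570, chromosome 2, 180597790 to 180622189), fell to 23.9 ± 6.04 CPM from 49.6 ± 10.6 CPM, a log2 fold change of -1.20 ± 0.12 (adjusted p = 0.0347, 4 of 4 mutants below all wild types). These were the 2 genes of 17616 that passed; 819 had an unadjusted p under 0.05, DESeq2 called 41 (13 higher, 28 lower) and the table of the authors has 17. Groups did not overlap for 3.43% of genes, where chance gives 2.86%.

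Of 44 lists tested in cerebellum P42, 15 were called, 4 higher and 11 lower, again with no list member past the gene test over all genes. Choroid plexus and ependymal markers were lower for all but 1 of 20 members, with a median of -1.02 (adjusted p = 4.5e-12, but 0.328 with an estimated correlation; 1 over the list alone). Ttr, the transthyretin gene of the choroid plexus, had 596 ± 403 CPM in mutants and 1626 ± 396 CPM in wild types, a log2 fold change of -1.72 ± 0.87 (adjusted p = 0.967), and Kl had -2.12 ± 0.66 (adjusted p = 0.967). Mutant replicate 1 had a mean choroid plexus level of -2.96 and the other mutants -0.82 to -0.60; without replicate 1 the median was -0.64, and without replicate 2 it was -1.76. Blood and erythroid markers were lower for all of 7 members (median -2.48, adjusted p = 3.2e-09, but 0.286 with an estimated correlation; 7 fell over the list alone), with Hba-a1, a hemoglobin gene, at -2.70 ± 0.56 (adjusted p = 0.700). MHC class II genes were lower for all but 1 of 8 (median -0.88, or -0.58 without the sex term, adjusted p = 0.000627, but 0.316 with an estimated correlation; 1 over the list alone). With the choroid plexus level as a covariate the MHC class II median was -0.21 (adjusted p = 0.588) and the call was lost.

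Higher lists in cerebellum P42 included ATF4 targets (33 of 34 members, median 0.50, adjusted p = 6.5e-12, but 0.773 with an estimated correlation; 6 over the list alone), p53 targets (19 of 23, median 0.44, adjusted p = 1.3e-06, but 0.316 with an estimated correlation; 6 over the list alone) and the aminoacyl-tRNA synthetases (19 of 23, median 0.21, adjusted p = 4.5e-07, but 0.286 with an estimated correlation; 2 over the list alone). Nars, the asparaginyl-tRNA synthetase gene, had 0.46 ± 0.10 (adjusted p = 0.727) and Trib3, an ATF4-induced pseudokinase gene, 2.39 ± 0.63 (adjusted p = 0.863). Mitochondrially encoded genes were the remaining higher list (11 of 12, median 0.32, adjusted p = 0.0307, but 0.834 with an estimated correlation). The mitochondrial call was lost when any of 4 single libraries was left out. The ATF4 level was 1.15 and 0.71 in mutant replicates 1 and 3 and 0.02 and 0.09 in replicates 2 and 4, with wild types between -0.07 and 0.06; without replicate 1 the ATF4 median was 0.18 and the p53 median 0.25. With the choroid plexus level as a covariate the ATF4 median was -0.11 (adjusted p = 0.508), the p53 median 0.27 (adjusted p = 0.556) and the synthetase median 0.13 (adjusted p = 0.354), and these 3 calls were lost. In that fit 7 lists were called and Col9a3 was not (-1.25, adjusted p = 0.149), leaving 1 gene. Col9a3 also missed the threshold without mutant replicate 1 (adjusted p = 0.0802) or 2 (0.308), without wild type replicate 1, 2, 3 or 4 (0.183, 0.244, 0.222 and 0.683), without the sex term (0.912) and with the replicate block (-1.07, adjusted p = 0.9998).

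**Figure D2:**
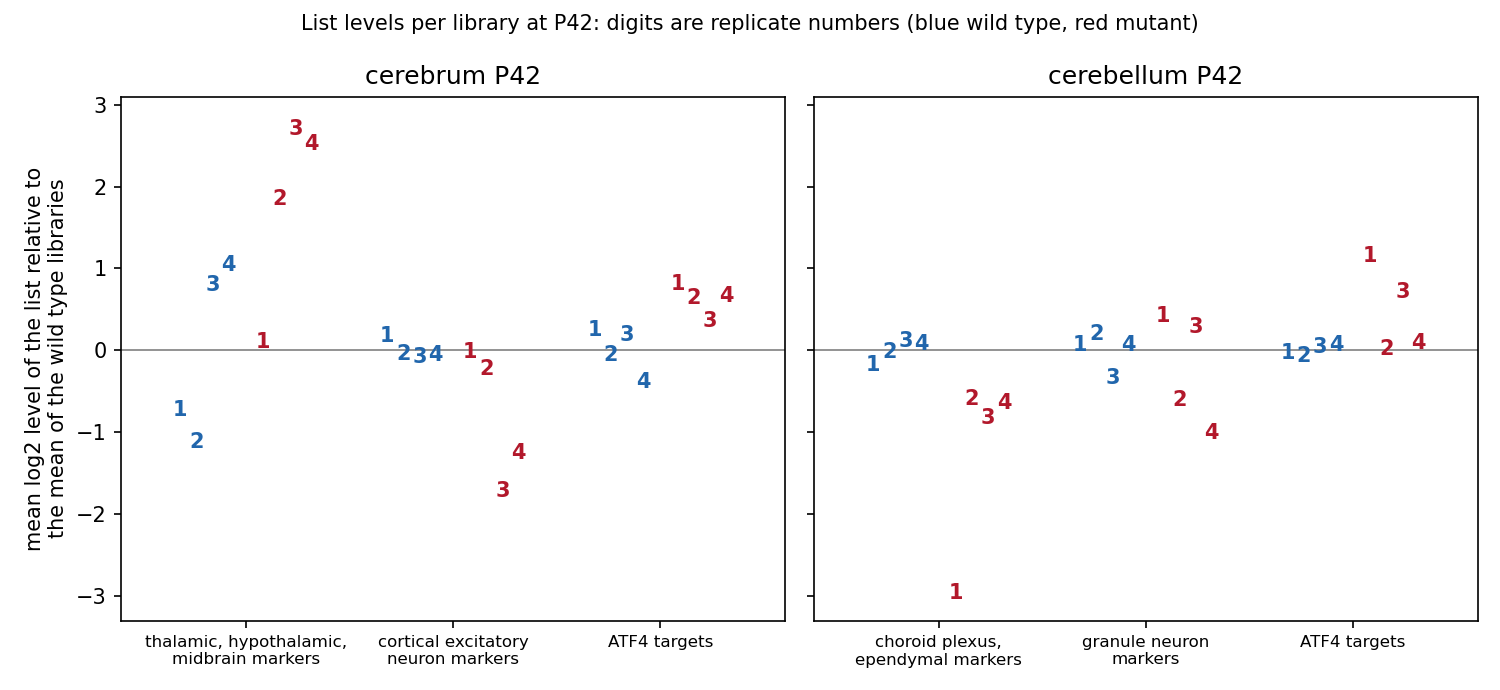
Mean log2 level of marker lists per library at P42 relative to the mean of the wild types (vertical axis), for cerebrum (left) and cerebellum (right); digits are replicate numbers, red for mutants and blue for wild types. Mutant replicates 3 and 4 lie at 2.70 and 2.52 for deep region markers in cerebrum P42, and mutant replicate 1 at -2.96 for choroid plexus markers in cerebellum P42.

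In cerebrum at P75, 2502 of 17523 genes changed, 1342 higher and 1160 lower. DESeq2 called 3084 (1579 higher, 1505 lower), of which 2496 were shared, and 2486 are also called in the table of the authors, which has 3128 (1612 higher, 1516 lower). The rises were larger: 608 genes rose at least 2-fold and 37 fell at least 2-fold. Groups did not overlap for 20% of genes, where chance gives 2.86%. The count was 1356 without mutant replicate 1 and 1634 without wild type replicate 4. Scaling by library size alone shifted the median of all genes to 0.11 and called 2860 genes (2313 higher, 547 lower), so the balance of rises and falls, unlike the number called, depends on the scaling.

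Genes induced by interferon moved together in cerebrum P75. All 67 measured interferon-stimulated genes rose, with a median log2 fold change of 3.0 (adjusted p = 1.1e-53, but 0.172 with an estimated correlation). Oasl2, an antiviral oligoadenylate synthetase-like gene, rose from 4.79 ± 0.824 to 146 ± 70.6 CPM (4.93 ± 0.33, adjusted p = 1.1e-06), Ifit3 by 4.2 ± 0.29 and Gbp3 by 3.62 ± 0.25. Cxcl10, a chemokine that draws T cells (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), rose from 0.493 ± 0.426 to 33.1 ± 16.4 CPM (6.03 ± 0.49); the log2 fold change was 6.67 without wild type replicate 1. Ifi206 had no count in wild types and was at least 78.7-fold higher, and Ifi211 had a ratio of 77.1 (95% interval 26.1 to 377). Cytosolic RNA and DNA sensors rose for 15 of 28 members (median 0.77, adjusted p = 6.6e-10, but 0.172 with an estimated correlation; 18 over the list alone), led by Irf7 (4.74 ± 0.34), Ifih1 (2.42 ± 0.22) and Ddx58 (2.61 ± 0.25), a transcription factor of the interferon response and a pair of RNA receptors. Of the 29 symbols of this list 14 are also in another list, among them these 3, which the interferon list holds too, so the lists are not independent. MHC class I genes rose for 19 of 20 (median 2.02, adjusted p = 4.4e-19, but 0.175 with an estimated correlation; 20 over the list alone), with H2-K1 at 2.38 ± 0.24 and Tap1 at 3.02 ± 0.27.

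Glial and inflammatory markers followed in cerebrum P75. Pan-myeloid markers rose for 23 of 25 (median 1.46, adjusted p = 2.9e-16, but 0.191 with an estimated correlation; 25 over the list alone) and disease-associated microglia markers for 24 of 33 (median 0.99, adjusted p = 2.8e-12, but 0.228 with an estimated correlation; 25 over the list alone). Itgax, an integrin gene, rose by 5.55 ± 0.74 and Cst7, a cystatin gene, by 5.91 ± 0.80, or 7.25 without wild type replicate 1. Homeostatic microglia markers rose for 7 of 21 (median 0.41, adjusted p = 0.000302, but 0.409 with an estimated correlation; 12 over the list alone), with Tmem119 at 0.64 ± 0.12. Complement genes rose for 12 of 17 (median 1.3, adjusted p = 1.5e-09, but 0.179 with an estimated correlation; 15 over the list alone), C4b from 32.0 to 258 CPM (3.01 ± 0.25). Chemokine and cytokine genes rose for 12 of 16 (median 2.05, adjusted p = 6.3e-08, but 0.175 with an estimated correlation), Ccl5 by 5.65 ± 0.70, or 7.73 without wild type replicate 1, while Cx3cl1, the neuronal fractalkine gene, fell by 0.42 ± 0.09. Reactive astrocyte markers rose for 21 of 31 (median 1.15, adjusted p = 5.5e-14, but 0.179 with an estimated correlation; 25 rose and 1 fell over the list alone), while astrocyte identity markers had 1 that rose, 1 that fell and a median of 0.07 (adjusted p = 0.365). Of the 32 reactive astrocyte symbols, 9 are also in another list, among them Cxcl10 and C4b.

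Stress and damage programs in cerebrum P75 came next. ATF4 targets rose for 33 of 36 (median 0.92, adjusted p = 1.3e-34, but 0.117 with an estimated correlation; 34 over the list alone), among them Stc2 (2.54 ± 0.16), Ddit3 (1.80 ± 0.12), which encodes CHOP, and Shmt2 (1.54 ± 0.10). Targets of p53 rose for 18 of 24 (median 0.85, adjusted p = 3.9e-15, but 0.172 with an estimated correlation; 19 rose and 1 fell over the list alone), with the proapoptotic genes Bbc3 (1.86 ± 0.14) and Pmaip1 (2.60 ± 0.27). Death mediators rose for 11 of 23 (median 0.51, adjusted p = 2.8e-07, but 0.191 with an estimated correlation; 12 over the list alone). Aminoacyl-tRNA synthetases rose for 12 of 23 and fell for 1 (median 0.51, adjusted p = 1.8e-11, but 0.117 with an estimated correlation; 15 rose over the list alone), with Aars at 0.77 ± 0.07 and Nars at 0.73 ± 0.07 higher and Farsb, a subunit of phenylalanyl-tRNA synthetase, at -0.46 ± 0.09. Replication-dependent histone genes rose for 16 of 24 (median 2.13, adjusted p = 8.1e-12, but 0.179 with an estimated correlation, 18 over the list alone). Hist1h2ah had no wild type count and was at least 57.4-fold higher, and Hist1h2bk had a ratio of 182 (95% interval 50.0 to 1506). Of the 68 genes of this list, only 24 had enough counts to be tested in these polyA-selected libraries. Whether histone RNA rose in total, or only the part of it with a polyA tail, was not tested. Proliferation genes rose for 6 of 18 (median 0.76, adjusted p = 3.0e-05, but 0.209 with an estimated correlation; 10 over the list alone), with Mki67 at 1.3 ± 0.27. Unfolded protein response genes of the endoplasmic reticulum were not called (adjusted p = 0.0504), with 1 that rose, Herpud1 (0.57 ± 0.10), which the ATF4 list also holds, and 2 that fell.

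Neuronal and metabolic groups were lower in cerebrum P75. Pan-neuronal markers fell for 16 of 25 (median -0.32, adjusted p = 1.7e-11, but 0.179 with an estimated correlation; 21 fell and 1 rose over the list alone), for example Snap25, a vesicle fusion protein gene (-0.45 ± 0.09), and Stmn2 (-0.54 ± 0.08). Synaptic genes fell for 18 of 42 (median -0.30, adjusted p = 4.0e-16, but 0.179 with an estimated correlation; 32 over the list alone), with Syn1 at -0.45 ± 0.08. Excitatory neuron markers fell for 15 of 27 (median -0.31, adjusted p = 6.2e-10, but 0.190 with an estimated correlation; 20 over the list alone), with Camk2a, a synaptic kinase gene, at -0.65 ± 0.11. With library size alone the synaptic and excitatory medians were -0.19 and -0.21. Striatal projection neuron markers fell for 8 of 19 (median -0.44, or -0.29 without mutant replicate 2, adjusted p = 1.5e-09, but 0.203 with an estimated correlation; 10 over the list alone), with Drd2, a dopamine receptor gene, at -0.88 ± 0.12. Cholesterol biosynthesis genes fell for 18 of 25 (median -0.58, adjusted p = 2.1e-16, but 0.117 with an estimated correlation; 20 over the list alone), with Sqle, squalene epoxidase, at -0.85 ± 0.09. Mitochondrially encoded genes fell for 11 of 13 (median -0.67, adjusted p = 2.8e-12, but 0.117 with an estimated correlation), with mt-Co2 at -0.92 ± 0.10. Nuclear-encoded oxidative phosphorylation genes were called lower as a list (18 of 77 higher, median -0.08, adjusted p = 0.0141, but 0.687 with an estimated correlation), with 1 that rose, Cox6a2 (0.89 ± 0.15), and 0 that fell. That call was lost with library size alone (median 0.02, adjusted p = 0.132), without mutant replicates 1 and 2 (adjusted p = 0.0714 and 0.346) and without wild type replicates 1 and 3 (adjusted p = 0.0802 and 0.281); the medians were -0.045, -0.038, -0.049 and -0.035, and -0.14 without wild type replicate 2. The largest falls of single genes were Wnt2 (-1.73 ± 0.32), Ackr2 (-1.58 ± 0.37) and Clspn (-1.37 ± 0.23), each with fewer than 4 CPM in wild types, and among abundant genes Ano3 (-1.29 ± 0.13, from 142 to 57.9 CPM).

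Myelin and mature oligodendrocyte genes were not called in cerebrum P75 (median -0.04 with TMM and 0.06 with library size alone, adjusted p = 0.0584): of 46, Apod rose (0.82 ± 0.16) and 3 fell. Lpar1, a lysophospholipid receptor gene, was the clearest fall (-0.41 ± 0.10), and it missed the threshold with library size alone (adjusted p = 0.0540). The other falls, Cryab and Ugt8a, also missed it with that scaling (adjusted p = 0.0892 and 0.132). Precursor markers had 1 that rose, Gpnmb (1.52 ± 0.28), which is also a microglial gene, and 3 that fell. Those falls, Gpr17, Tnr and Pdgfra, missed the threshold with library size alone (adjusted p = 0.144, 0.157 and 0.0597). Endothelial and mural markers rose for 10 of 29 (median 0.26, adjusted p = 1.4e-07, but 0.117 with an estimated correlation; 14 over the list alone), with Vwf at 0.94 ± 0.10. Of 18 subunits of RNA polymerase III, Crcp (0.38 ± 0.10) and Polr3e (0.33 ± 0.10) rose and Polr3k (-0.44 ± 0.10) fell, and the list was not called (adjusted p = 0.480). Crcp missed the threshold without mutant replicate 1 and wild type replicates 1 and 4 (adjusted p = 0.0970, 0.0757 and 0.0603). Polr3e missed it without mutant replicates 1 and 2 and wild type replicates 2, 3 and 4 (adjusted p = 0.121, 0.107, 0.0678, 0.0847 and 0.103). The thalamic, hypothalamic and midbrain markers that were higher at P42 had a median of -0.03 at P75 (0.07 with library size alone, adjusted p = 0.510).

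**Figure D3:**
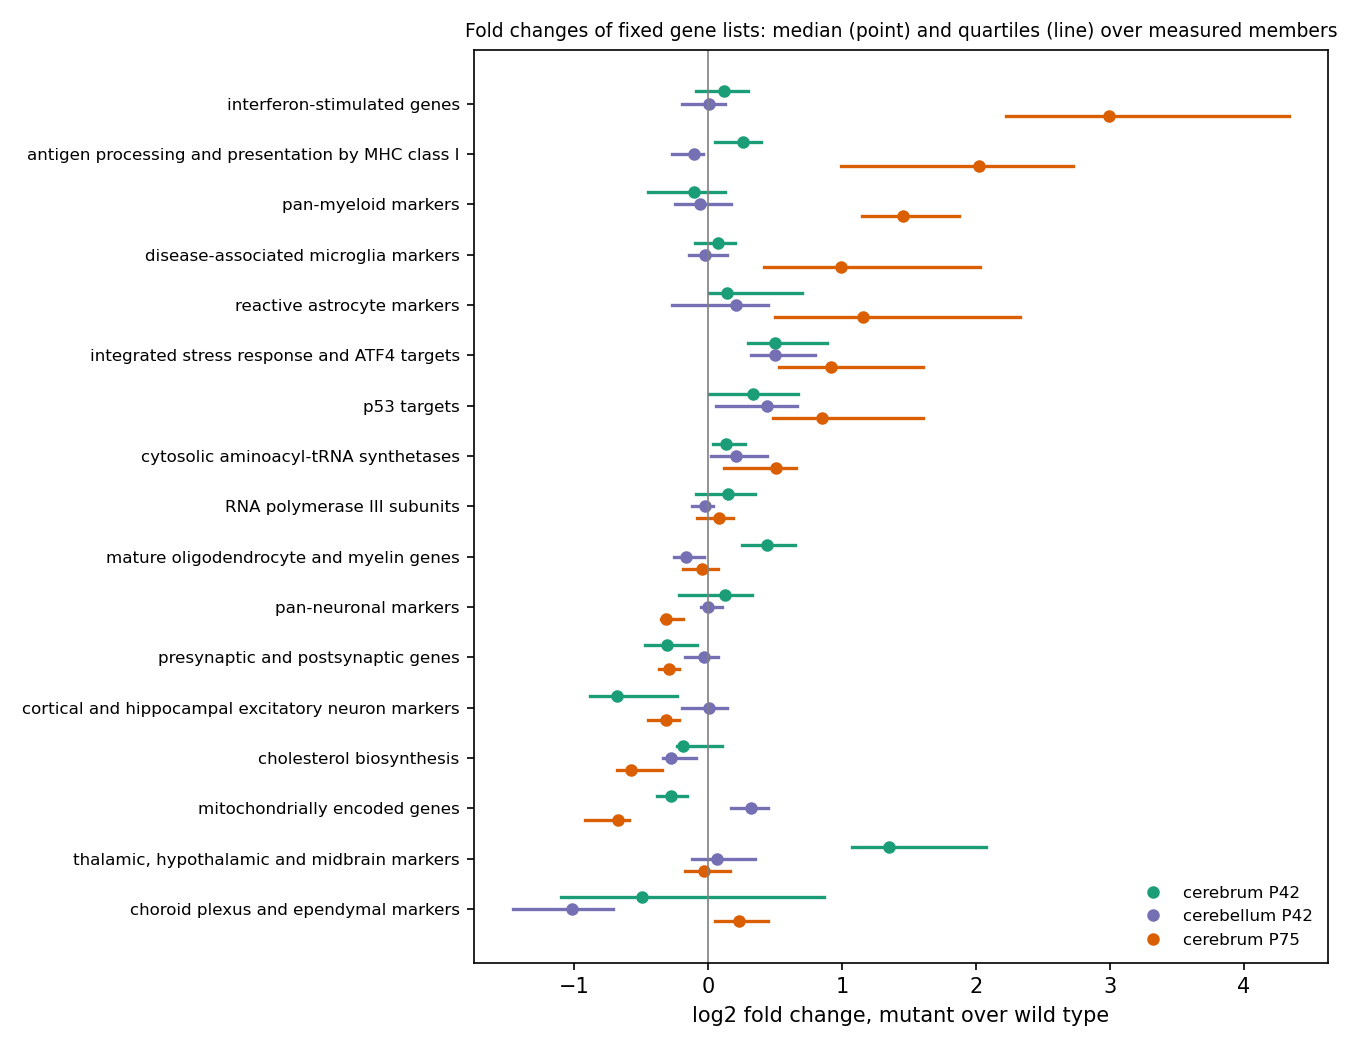
Log2 fold changes of mutant over wild type (horizontal axis) for fixed gene lists (vertical axis) in the 3 comparisons; points are medians and lines quartiles over measured members. The interferon list has medians of 0.12, 0.01 and 3.0 in cerebrum P42, cerebellum P42 and cerebrum P75, and the ATF4 list 0.50, 0.50 and 0.92; the cerebellar interferon median is -0.003 with library size alone.

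Noncoding RNAs made by RNA polymerase III are the direct products of the enzyme but lie outside polyA selection. Of 11 such genes in the tables, 10 had at most 10 counts over the 24 libraries together, so no change was detectable at this depth. The exception was Rn7sk, the 7SK RNA gene, at 0.795 ± 0.290 against 1.72 ± 1.14 CPM in cerebrum at P75 (log2 fold change -1.21 ± 0.45, adjusted p = 0.089), 26.7 ± 22.4 against 60.8 ± 35.8 CPM in cerebellum (-1.02 ± 0.47, adjusted p = 0.967) and 16.1 ± 9.32 against 12.2 ± 2.73 CPM in cerebrum at P42 (0.30 ± 0.32, adjusted p = 0.681).

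Whether the genotype effect differed between P42 and P75 was tested directly in the 16 cerebrum libraries. All mice received tamoxifen at P28, 14 days before P42 and 47 days before P75, so age and time since induction cannot be told apart. The genotype effect differed for 263 of 19273 genes, 201 more positive and 62 more negative at P75. Interferon-stimulated genes made up 54 of the 201: Oasl2 differed by 4.49 ± 0.43 (adjusted p = 0.000117), Isg15 by 4.49 ± 0.46 and Ifit3 by 3.81 ± 0.38, with Isg15 at -0.09 ± 0.31 at P42. Also more positive at P75 were 11 of 25 pan-myeloid markers, 9 of 20 MHC class I genes, 7 of 21 homeostatic microglia markers, 3 of 24 p53 targets and 2 of 36 ATF4 targets, where all genes gave 201 of 19273. Slitrk6 and Synpo2 differed the other way, by -2.45 ± 0.28 and -2.14 ± 0.25, and had -0.13 ± 0.16 and -0.02 ± 0.09 at P75. More negative at P75 were also 4 of 28 thalamic, hypothalamic and midbrain markers (13 over the list alone, median difference -1.43) and 2 of 13 mitochondrially encoded genes. All genes gave 62 of 19273. How far a difference in dissection at P42 enters these differences was not tested. The count was 1169 without P42 mutant replicate 1, and 124, 144, 159, 153, 158 and 166 without P75 mutant replicates 1 and 2, P75 wild type replicates 1, 3 and 4, and P42 mutant replicate 4; males alone gave 135 and DESeq2 670.

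Whether cerebrum and cerebellum responded differently at P42 was tested in the same way. Of 19614 genes, 0 passed in edgeR, with 1213 at an unadjusted p under 0.05 and 8 called by DESeq2. Synpo2 had the smallest adjusted p (0.130), with a difference of -1.93 ± 0.29, followed by Slitrk6 (-2.83 ± 0.51, adjusted p = 0.409). Without wild type replicate 1 of the cerebrum, 2 genes passed. Esr1 differed by 1.58 ± 0.54 (adjusted p = 0.732).

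Genes changed in more than 1 comparison were counted among genes tested in both. Esr1 was the sole gene shared, between cerebellum at P42 and cerebrum at P75 (1 higher, 0.0720 expected by chance, one-sided Fisher exact p = 0.0720). The cerebrum comparisons shared 0 genes, and 28 higher and 30 lower by DESeq2, where 13.7 and 5.92 are expected of independent lists. The 28 include Esr1, Mthfd2, Chac1, Sesn2 and Cdkn1a, and also Prkcd and Avp of the deep region list; the 30 include Etv1 and Bcl11b of the excitatory neuron list, Hapln1, C1ql3 and Ano3. How far a difference in dissection at P42 enters these counts was not tested. Of the genes called at P75, 1681 of 2374 (70.8%) had the same sign in cerebrum at P42 and 1338 of 2307 (58.0%) in cerebellum; genes are not independent replicates, so these shares carry no test.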

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

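Tests chosen after the results were seen were those of Esr1, of deep region tissue by cortical markers, of a smaller share of neurons, and of scaling in its present form. The deep region covariate in the test of the ATF4 targets was also chosen after the data were seen. A library was flagged when its gap to the nearest of the other 3 in its group took up most of the range of the group. Chance flags about 1 in 20 groups; of 202 groups tested 17 were flagged, against 10.1 expected.

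Esr1 counts were higher in every mutant library of the 3 comparisons, and the lowest mutant lay 4.35, 22.6 and 9.79 times above the highest wild type. The tables argue against 1 common fold induction of the endogenous gene: the log2 fold changes of cerebellum and cerebrum at P42 differed by 1.58 (95% interval 0.506 to 2.66). Reads of an estrogen receptor fusion transgene, as in tamoxifen-inducible Cre lines, could give a rise of similar size in both tissues, and the ratio of the rises was 1.33 (95% interval 0.974 to 1.80) while wild type levels had a ratio of 0.406. The labels neither name the Cre driver nor say whether wild types carried it, and no reads were available to look for a fusion, so the transgene stays open, as does an induction of Esr1 that differs between tissues. In either case the Esr1 level separated the libraries labelled mutant from those labelled wild type in all 24, which does not show the Polr3a allele itself.

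In cerebrum at P42 thalamic, hypothalamic and midbrain markers were higher in mutants, most in replicates 3 and 4. More tissue from below the cortex in the mutant dissections could give this, and would lower the share of cortical transcripts. Cortical and hippocampal excitatory neuron markers had a median of -0.68 (95% interval over genes -0.848 to -0.430). That interval does not measure the spread between libraries, and the median moved when libraries were left out, as given above. Lower expression of those genes in the cortex would give the same sign, so dissection stays open. A difference in dissection between a few libraries that fell on the genotypes by chance stays open too, since the exact permutation p of the mean marker level was 0.0857, where 0.0286 is the smallest possible. For ATF4 targets the median did not fall with the marker level as a covariate: it was 0.65 (95% interval over genes 0.461 to 1.01), against 0.50 without it. This argues against dissection as the whole cause of the ATF4 rise, as far as an interval over genes can tell. A change in the brain regions themselves stays open and was not tested.

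In cerebrum at P75 the 65 pan-neuronal and synaptic genes had a median of -0.29 (95% interval over genes -0.335 to -0.249). The tables argue against a trend with gene length and expression level as the whole cause, since 0% of 10000 random lists matched on both had a median as low (lowest -0.23). The middle of the matched medians was -0.12 and not 0, so a part of the size may go with length and level. With library size alone the median was -0.19 (95% interval over genes -0.228 to -0.142). Genes that rise also add to library size, so this value alone cannot argue against scaling by the genes that rose. A scaling factor moves all genes of a library alike, and with library size alone the median of all genes was 0.11. With either scaling the neuronal and synaptic median lay below that of all genes, so these genes fell relative to the typical gene. Whether they fell in absolute amount is not decided. A part of the size of their median depends on the scaling. The test set beforehand, the median of all tested genes (0.00313), decides nothing, since TMM holds it near 0 in any case. The medians of endothelial, astrocyte, precursor and myelin lists lay 0.305 apart (0.26, 0.07, -0.03 and -0.04). The 95% interval over genes of the endothelial list did not overlap those of the others. As far as an interval over genes can tell, this argues only against a smaller share of neurons with all of these types kept in proportion. A change in cell types that rose, such as microglia, a smaller share of neurons with unequal change in other types, and lower expression in neurons stay open.

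Other ways to split the same 8 libraries into 4 and 4 were counted for each result. For cerebrum at P75, 1 of 35 splits, the real one, gave as many genes (2502, against 0 in the highest other). This is the smallest share that 35 splits can give, so it argues against chance for that count without excluding it. For its lists 5 of 35 gave as many (31, highest other 32). The other 4 each keep 3 of the 4 mutants together, so they hold a part of the genotype difference, and splits with 2 mutants on each side gave at most 28. The list count therefore does not exclude chance, and says little about it either way. For cerebrum at P42, 2 of 34 splits gave as many genes (3, highest other 67) and 5 of 34 as many lists (18, highest other 23). For cerebellum at P42, 2 of 35 gave as many genes (2, highest other 1000) and 17 of 35 as many lists (15, highest other 22). The split with 1000 genes set mutant replicates 1 and 3 with wild type replicates 2 and 4 against the rest, so structure other than genotype is present in the cerebellum libraries. Chance is not excluded for any of these P42 counts. For the difference between tissues the real count was 0, which all 60 of 60 drawn assignments reach (highest other 5), so their number decides nothing; for the difference between ages 2 of 60 did (263, highest other 323), a share under 0.05.

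The genotype effect differed between P42 and P75 in cerebrum for 263 genes by the interaction test. The smallest p values belonged to Oasl2 (4.49), Isg15 (4.49), Ifit3 (3.81), Gbp3 (3.51) and Rnf213 (3.06), more positive at P75, and to Slitrk6 (-2.45), Synpo2 (-2.14), Adarb1 (-0.96), Abhd12b (-3.55) and Rims3 (-1.09), more negative at P75.

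Libraries far from the other 3 of their group were these. In wild type cerebrum at P75, replicate 3 had the highest total (20.5 in units of 1000000, others 15.7 to 16.3) and the lowest homeostatic microglia level (-0.11). Replicate 2 had the highest mitochondrial share (5.64%, others 4.44 to 4.61%) and the highest Ano3 level (189 CPM). Replicate 4 had the lowest immediate early gene level (-0.41), and replicate 1 the highest CPM of Cst7 (0.631) and Ccl5 (0.379). In mutant cerebrum at P75, replicate 2 had the highest CPM of Clspn (1.61) and replicate 1 the lowest of Vmn2r84 (0.557). In mutant cerebrum at P42, replicate 4 had the highest level of MHC class II genes (0.0106) and of reactive astrocyte markers (0.41). In wild type cerebrum at P42, replicate 1 had the highest excitatory neuron level (0.18) and replicate 4 the lowest histone level (-0.44). In cerebellum at P42, mutant replicate 1 had the lowest choroid plexus level (-2.96), and among wild types replicate 4 had the lowest mitochondrial share (3.05%) and the highest MHC class II level (0.42), and replicate 2 the lowest myelin level (-0.32).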

How the results depend on the processing

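Scaling by library size alone, marker levels as covariates, leaving out mutant replicates 3 and 4 together, males only and fry were chosen after the data were seen. The genes called in cerebrum at P75 kept their number within 1.5 times except at an adjusted p under 0.01 (1086) and without mutant replicate 1 or wild type replicate 4 (range over single libraries left out 1356 to 2783). The P42 gene counts moved with the choices below, and the cause was not tested; in cerebellum the 2 genes stayed the same with a stricter filter and with library size alone, and 1 of them, Esr1, was called in every fit.

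In cerebrum at P42 the 3 genes became 233 with DESeq2, 1312 without a filter, and 0 with a stricter filter, without the sex term, with library size alone, with the deep region covariate, without mutant replicates 3 and 4, and at an adjusted p under 0.01; single libraries left out gave 0 to 11. In cerebellum the 2 genes became 41 with DESeq2, 153 without a filter, and 1 without the sex term, with the choroid plexus covariate and at an adjusted p under 0.01; single libraries left out gave 1 to 2. The tissue difference went from 0 to 8 with DESeq2 and 279 without a filter (0 to 2 with single libraries left out). The age difference went from 263 to 670 with DESeq2, 1176 without a filter and 135 in males only (124 to 1169).

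Lists went from 18, 15 and 31 to 0, 0 and 0 with an estimated correlation. For many called lists the estimate lay far above the preset 0.01, as for interferon-stimulated genes in cerebrum P75 (0.866) and myelin in cerebrum P42 (0.608). The adjusted p values of such lists with the preset are too small. Calls were also lost where the estimate lay below the preset, so a higher correlation does not account for every loss. Examples are tRNA processing in cerebrum P75 (estimate -0.00406, adjusted p = 0.117) and MHC class II in cerebrum P42 (-0.0442, adjusted p = 0.542). Interferon-stimulated genes in cerebrum P75 were not called with an estimated correlation, although all 67 passed the gene test. A call lost in this way therefore does not by itself tell a changed list from an unchanged one. With fry the called lists numbered 0, 0 and 26. With the choroid plexus covariate 7 lists were called in cerebellum. Of the 15 called without it, 3 kept their call and direction, and myelin was called in the other direction (0.45, adjusted p = 1.6e-05). Among the rest, pan-neuronal markers were newly called (0.34, adjusted p = 0.0149). With each single library left out 15 to 23, 10 to 16 and 29 to 33 lists were called, and 10 of 18, 6 of 15 and 26 of 31 kept their call throughout, as did 0 of 3, 1 of 2 and 126 of 156 called genes named by rule.

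Shared genes went from 0 to 2 higher between the cerebrum comparisons at an adjusted p under 0.1, and to 28 higher and 30 lower with DESeq2. Between cerebrum and cerebellum at P42 they went to 1 higher under 0.1, and to 4 higher and 2 lower with DESeq2. Between cerebellum and cerebrum at P75 they went from 1 to 8 higher and from 0 to 2 lower with DESeq2.

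Directions reversed as follows, and the cause was not tested. With the deep region covariate in cerebrum P42: striatal 0.51, deep region -0.040 and immediate early genes 0.066. With the choroid plexus covariate in cerebellum P42: ATF4 targets -0.11, unfolded protein response 0.0092, myelin 0.45, oligodendrocyte precursors 0.12, cholesterol 0.26, pan-neuronal 0.34 and nuclear oxidative phosphorylation 0.028. The deep region list (-0.040) and the choroid plexus list (0.040) also changed sign. Each supplied its own covariate, so these values follow from the model and show nothing about genotype. In cerebellum P42 myelin ran from -0.63 to 0.087 (without mutant replicate 1) and Bergmann glia from -0.23 to 0.0086 (without wild type replicate 2) with single libraries left out. In cerebrum P75 nuclear oxidative phosphorylation was 0.024 with library size alone and ribosomal proteins ran from -0.0058 (without wild type replicate 2) to 0.11. Hbb-bs ran from -1.85 to 1.28 and Hba-a1 from -1.71 to 1.09, each lowest without mutant replicate 3.

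Libraries share replicate numbers, but the labels do not say that same-numbered animals are related, so the numbers were not treated as pairs. Correlations of same-numbered mutants and wild types ran from -0.599 to 0.156 at P42 and from 0.0258 to 0.141 at P75. Different-numbered pairs at P75 ran from -0.0989 to 0.0502, and each same-numbered pair had the highest correlation of its libraries. A link between same-numbered libraries at P75 therefore stays open. With the replicate number as a block (replicate block), 8 genes were called in cerebrum at P42, 1 in cerebellum and 3537 in cerebrum at P75; Wnt3 (1.94, adjusted p = 0.0542) and Col9a3 (-1.07, adjusted p = 0.9998) lost their calls.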

Other observations

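The count of genes that moved the same way in all 3 comparisons was chosen after the data were seen. Of 16288 genes tested in all, 37 were higher and 9 lower at an unadjusted p under 0.05 in each, where 3.90 and 3.23 are expected if the comparisons were independent. The 37 hold 10 of 34 ATF4 targets (Fisher exact p = 1.2e-19), 5 of 23 aminoacyl-tRNA synthetases (Fisher exact p = 1.5e-09) and 4 of 23 p53 targets (Fisher exact p = 1.9e-07); members of a list are correlated, so these p values are too small. In cerebellum P42 these lists depend on the libraries and the model: without mutant replicate 1 the ATF4 median went from 0.50 to 0.18 and the p53 median from 0.44 to 0.25. With the choroid plexus covariate the ATF4 median was -0.11, and the ATF4, synthetase and p53 calls were lost (adjusted p = 0.508, 0.354 and 0.556). A response common to both tissues is therefore not established. Trib3 had 2.09 ± 0.70, 2.39 ± 0.63 and 2.64 ± 0.24 in cerebrum P42, cerebellum P42 and cerebrum P75, and Cdkn1a, the p21 gene, 1.12 ± 0.29, 1.3 ± 0.42 and 1.42 ± 0.15. Among genes lower in all, Ldha, the lactate dehydrogenase A gene, had -0.55 ± 0.22, -0.53 ± 0.13 and -0.40 ± 0.08.

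The exact permutation p of the mean ATF4 target level was 0.0286 in cerebrum at P42, 0.0857 in cerebellum at P42 and 0.0286 in cerebrum at P75, where 0.0286 is the smallest that 4 against 4 libraries can give.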
